A study of Gossypium hirsutum with 6 samples.

How the data were processed

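The data were RNA-seq gene counts from whole roots of upland cotton (Gossypium hirsutum), an allotetraploid whose chromosomes fall into an A and a D subgenome. Roots came from M120, a line resistant to root-knot nematodes (Meloidogyne, sedentary parasites that induce galls and feeding cells in roots), and from C201, a susceptible line. Each line was sampled untreated and at 12 and 30 days after inoculation (DAI), which gave 6 GEO samples in 6 groups. The untreated samples carry the age label 0 DAI, although the protocol text describes un-inoculated roots lifted at both time points. Plant age of the untreated roots is therefore uncertain, and a difference between an inoculated and an untreated library also holds any effect of age or sampling time.

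Per the labels' protocols, total RNA was made into libraries with the NEBNext Ultra RNA kit and indexed for pooling. Per the submitters' processing notes, FastQC, Trimmomatic 0.30 and HISAT2 2.1.0 were used. The counting tool, its settings, the genome build and the annotation are not given in the sources used here. The deposited files hold raw, whole-number counts per gene without normalization, for 70478 gene identifiers and with 2 count columns per file, per the file headers. No row named anything other than a gene. All 12 columns were used.

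The labels speak of a replicated set of libraries and the file columns are numbered 1 and 2, so it was tested whether the columns of a file were separate libraries. In every file the second column summed to between 2.16% and 2.47% more than the first. Between the columns of a file, the variance of the counts was 2.24 to 2.39 times what binomial counting gives. That factor lay between 2.23 and 2.38 for the lowest genes used (at least 20 counts) and between 2.34 and 2.54 for genes with at least 2000. Between first columns of different files it rose over the same range from 5.01 to 107 in one pair of libraries and from 5.56 to 95.6 in another. The factor within files did not grow as it did between libraries, so the columns were taken as repeat readings of 1 library, their counts were summed, and n was 1 per group. Whether they are runs, or the mates of read pairs counted separately, is not stated. Since readings of 1 library already differed by more than binomial counting, the counting intervals used here are too narrow whatever the columns are. An analysis with the columns as replicates was added as an alternative after the data were seen. It did not pair columns by number between groups, although the second column was the larger in every file.

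The identifiers give a chromosome code and a serial number for 66434 genes (32032 on A and 34402 on D chromosomes) and a scaffold number for 4044 genes. None of them (0) matched the RefSeq gene table supplied for the species (assembly Gossypium_hirsutum_v2.1), and the files do not pair identifiers with names. The gene lists fixed before the data were examined (pathogenesis-related proteins, hormone pathways, cell wall, cell cycle, tissue markers and others) are patterns on product names and could not be formed. No list was tested, no gene is named by function, and at most 2 higher and 2 lower identifiers are printed per comparison. Gene order was taken from the serial numbers, without coordinates.

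Tests used edgeR 4.0.16 in R 4.3.3 with limma 3.58.1: TMM scaling, the filter of filterByExpr, quasi-likelihood F tests, and Benjamini-Hochberg adjustment at 0.05. The first fit had stage and line as additive terms, so that the 3 stages served as pairs of libraries, and tested M120 against C201, 12 DAI against untreated and 30 DAI against untreated in 49267 genes. Its 2 residual degrees of freedom are the line-by-stage interaction, which stands in for replicate spread. The second fit had line, inoculation and their interaction in 51507 genes. There the 12 and 30 DAI libraries of a line stood as its inoculated libraries, the residual (2 degrees of freedom) was the difference between them, and the lone untreated library was assumed to vary alike. Standard errors (SE) are the absolute log2 fold change over the square root of F. No source says how many plants entered a library, and p-values measure only the spread between these libraries.

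For 7 pairs of single libraries no p-value was computed. A gene was called higher or lower by a rule of size when the exact 95% interval (Clopper-Pearson, conditional binomial) of its TMM-scaled ratio lay wholly beyond 2-fold and it reached 1 CPM (the usual count scaled to library size) in either library. This rule compares libraries, not conditions. Where a gene had 0 counts in a library, the fold is taken against 3 counts per library. In the tests it is printed as at least, with the higher count taken as exact. For pairs the lower end of the counting interval is given with it. Intervals and bounds hold no error beyond counting. Correlations across genes used 28761 genes with a mean of at least 5 CPM, and genes are not independent replicates. Those of log2 ratios used log2 of CPM plus 0.5. Those between libraries, and the principal components, used log2 of CPM plus 2.

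Genes printed from a test were the largest log2 fold changes in each direction among those past the threshold with a mean log2 CPM of at least 1 and the same direction in every library pair the contrast spans. If fewer than 5 passed, those with the smallest unadjusted p were taken and said to fail. For a pair of libraries they were the largest ratios past the rule with at least 50 reads in the higher library, ranked with counts below 3 raised to 3, so that the order can differ from that of the printed ratios. These rules, the tests and most alternatives were set before the data were examined.

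Alternatives were DESeq2 1.42.0 size factors within edgeR, no filter on low counts, the DESeq2 Wald test, leaving out each library, a line test without the stage term, total-count scaling, a 4-fold rule and no CPM minimum. Added after the data were seen were the columns as replicates, counts divided by the mean variance factor of 2.31, libraries thinned to 7451819 counts, and a subgenome share under the other size factors. Gene position was tested with Fisher's exact test for each of 26 chromosomes. Scans along the identifiers used 100000 random gene orders. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

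On simulated counts for the line test (49267 genes), 100 of 100 genes changed 8-fold and 12 of 100 changed 2-fold were recovered, with 6 false calls among 118. For the C201 inoculation test (51507 genes) 13 of 100 and 0 of 100 were recovered, with 0 false calls. In both simulations all genes had the same dispersion (spread beyond counting), so recovery and false calls among real genes can differ. For the pair of C201 at 12 DAI and untreated (43183 genes) the rule of size recovered 200 of 200 genes changed 8-fold and took 0 unchanged genes. That simulation of the pair held counting error alone, without the variance factor between columns or any spread between plants. Its 0 is therefore no rate of false genes for real libraries. The 86 genes studied for a shared ratio had a simulated test of their own.

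Counts per library, both columns summed, ran from 7451819 to 34199400. A count of 3 corresponded to 0.403 CPM of the total in the shallowest library and to 0.0877 CPM in the deepest. Homeologs and tandem copies of this polyploid genome can share reads, and how the authors' counting treated such reads, or reads from overlapping genes on either strand, is not given in the sources used here.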

Results

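Root transcriptomes of a root-knot nematode resistant cotton line, M120, and a susceptible line, C201, were compared untreated and at 12 and 30 days after inoculation (DAI). Each of the 6 groups had 1 library, so no single group had a replicate. The C201 libraries held 21859883 counts untreated, 22698186 at 12 DAI and 7451819 at 30 DAI. The M120 libraries held 17733128, 30471332 and 34199400 counts in that order. Between 51516 and 56790 of 70478 genes had at least 1 count, and the 10 most abundant genes took 1.91% to 2.88% of the counts. Across genes, the libraries correlated with r between 0.767 and 0.95. The C201 30 DAI library had the 0.767 value, against M120 at 12 DAI, and the first principal component (53.8% of the variance) set it apart from the other 5.

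The first question was which genes differed between the resistant and the susceptible line on average over the stages. Of 49267 genes tested, 514 differed, 218 higher and 296 lower in M120. Their median absolute log2 fold change was 1.85, the same with the 13 genes that had no counts in one line set at their bound, and 116 differed by at least 8-fold. Gh_D07G1111, on chromosome D07, averaged 14 ± 5.54 CPM (SD, n = 3 stages) in M120 and had 0 counts in all C201 libraries, at least 59.7-fold higher (edgeR adjusted p = 0.00473). Gh_Sca005954G01, on an unplaced scaffold, averaged 4.46 ± 0.654 CPM in M120 against 0 counts in C201, at least 19.0-fold higher (edgeR adjusted p = 0.0194). In the other direction, Gh_D10G2075 averaged 6.13 ± 3.47 CPM in C201 and had 0 counts in M120, at least 53.0-fold lower in M120 (edgeR adjusted p = 0.0116). Gh_D08G0480 averaged 6.07 ± 1.87 CPM in C201 and had 0 counts in M120, at least 52.6-fold lower (edgeR adjusted p = 0.0107). In all, 15 genes had at least 10 reads in each M120 library and none in C201, and 4 genes showed the reverse. This rule counts reads, and the shallow C201 30 DAI library (7451819 counts) favours M120 in it. With at least 100 reads, 1 gene was read in M120 only and 0 in C201 only.

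The line test was the edgeR quasi-likelihood test with stage as a term, and 6016 genes passed an unadjusted p under 0.05. The count rested on few libraries: it was 2451 without C201 30 DAI, 2464 without M120 30 DAI, 1069 without the low-count filter and 1687 with the DESeq2 test. The balance of higher and lower turned in 3 settings, to 155 higher and 108 lower without C201 untreated (263 genes), 138 and 129 without M120 untreated (267), and 52 and 41 without the stage term (93).

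Taken stage by stage, the line differences recurred in separate libraries. By the rule of size, 874 genes were higher and 1118 lower in M120 than in C201 among untreated roots, 981 and 1051 at 12 DAI, and 2056 and 2150 at 30 DAI. The balance at the later stages depended on the scaling: with total counts in place of TMM, 1092 were higher and 962 lower at 12 DAI, and 2477 and 1736 at 30 DAI. With thinned libraries the split at 30 DAI was 1832 and 1586. With counts divided by the variance factor between columns, 1132, 1238 and 2554 genes passed in stage order. The untreated and 12 DAI comparisons share no library, and of the genes past the rule in both, 233 were higher, 379 lower and 18 opposite (13.2, 21.8 and 34.1 if independent). Across genes their log2 ratios correlated with r = 0.53 and Spearman's rho = 0.35. Between the untreated and 30 DAI comparisons, 343 were higher, 398 lower and 32 opposite (31.5, 41.6 and 74.1 if independent), with r = 0.45 and rho = 0.33. Agreement was weakest between those at 12 and 30 DAI, where 343 were higher, 252 lower and 74 opposite (38.8, 36.3 and 75.5 if independent), with r = 0.30 and rho = 0.16. At all 3 stages 172 genes were higher and 176 lower in M120, against 0.516 and 0.753 if independent. Among untreated roots Gh_D13G2155 had 2276 counts in M120 and 2 in C201, a ratio of 1381 (counting interval 382 to 11414). Gh_A03G0256 had 1 count in M120 and 2167 in C201, a 1785-fold difference in the other direction (320 to 70539). Gh_D13G2155 was among the genes past the line test over stages. Gh_A03G0256 was not, so its ratio describes untreated roots only.

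**Figure D1:**
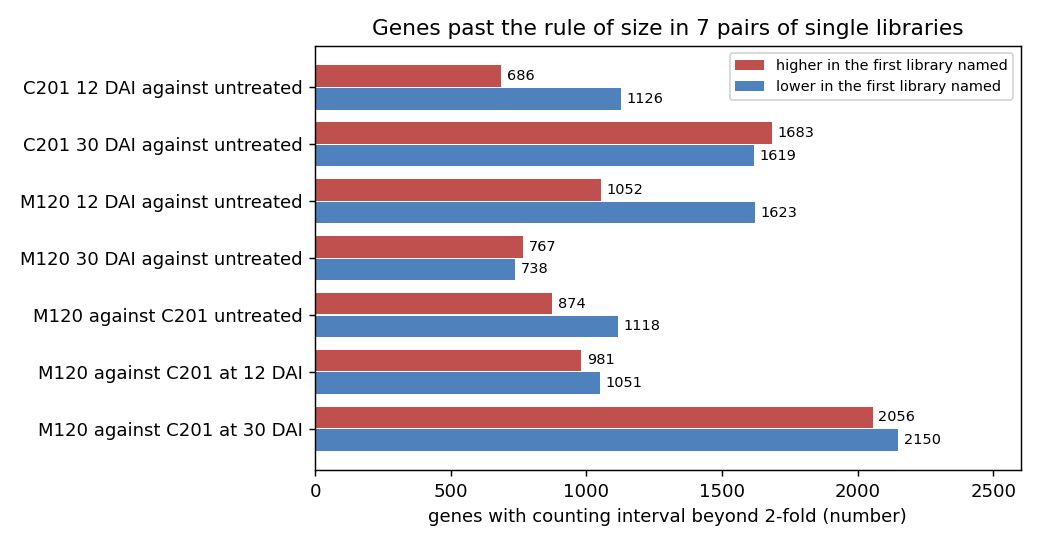
Number of genes past the rule of size (exact 95% counting interval of the ratio beyond 2-fold, at least 1 CPM in either library) in each of 7 pairs of single libraries, with genes higher in the first-named library in red and lower in blue. The 2 pairs with the C201 30 DAI library hold the most genes, 1683 higher and 1619 lower against untreated C201, and 2056 higher and 2150 lower for M120 against it. The balance of the lower 2 pairs turned with total-count scaling, to 1092 higher and 962 lower at 12 DAI and 2477 and 1736 at 30 DAI, and so did that of both response pairs at 30 DAI, to 1306 and 2038 in C201 and 715 and 801 in M120.

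The next question was what changed by 12 DAI. At this stage genes lower than in untreated roots outnumbered those higher in both lines. In C201, 686 genes were higher and 1126 lower by the rule of size, and in M120, 1052 were higher and 1623 lower. With counts divided by the variance factor, 957 genes passed in C201 and 1572 in M120. The lines moved together: 117 genes were higher in both and 369 lower in both, with 11 opposite, against 12.2, 30.3 and 38.5 if independent, and log2 ratios correlated across genes with r = 0.53 (rho = 0.48). With the lines as a replicate pair, 23 of 49267 genes fell and 0 rose, although other settings called genes in both directions. Log2 fold changes ran from -5.19 to -1.85 among the 22 with counts at 12 DAI. Gh_A02G0199 had 7.18 ± 3.53 CPM (SD, n = 2 lines) in untreated roots and 0 counts in both 12 DAI libraries, at least 62.8-fold lower (edgeR adjusted p = 0.0374). It stood at 13.3 ± 2.13 CPM at 30 DAI. Gh_D08G1123 fell by 5.19 on the log2 scale (SE 0.33, edgeR adjusted p = 0.0208), from 20.9 ± 6.30 CPM to 0.585 ± 0.240, and stood at 25.9 ± 16.5 CPM at 30 DAI.

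The 12 DAI test used the additive edgeR fit, with 5049 genes at an unadjusted p under 0.05, and its count was unstable. It was 0 without M120 12 DAI and 5, all lower, without M120 untreated. Both directions were called without C201 untreated (4 higher, 46 lower), C201 12 DAI (10 and 19), C201 30 DAI (1343 and 1956) or M120 30 DAI (1413 and 1919), without the low-count filter (27 and 188) and with DESeq2 (140 and 537). Age and inoculation were not separated in these libraries.

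Single-line ratios at 12 DAI held larger changes. In M120, Gh_D06G0237 went from 0 to 1549 counts (49.5 CPM), 301-fold higher against the count used for 0 (counting interval from 245). Its near neighbour by serial number, Gh_D06G0233, went from 0 to 354 counts, 68.9-fold higher on the same basis (counting interval from 55.7). Gh_D06G0237 had 0 counts in C201 at 12 DAI. In M120, Gh_D02G0260 went from 309 counts to 0, 176-fold lower against the count used for 0 (counting interval from 143). In C201, Gh_A06G1379 had 80 counts at 12 DAI against 2 untreated, a ratio of 39.4 (counting interval 10.6 to 331). Gh_D03G1605 went from 4567 to 23 counts in C201, 202-fold lower (134 to 319), and Gh_D10G2219 from 414 to 2, 210-fold lower (57.8 to 1742). These ratios had no replicate check.

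At 30 DAI the size of the response differed between the 2 lines' libraries. In C201, 1683 genes were higher and 1619 lower than untreated, and in M120, 767 were higher and 738 lower. The SD of log2 ratios over genes with a mean of at least 5 CPM was 0.71 in C201 and 0.44 in M120. Across lines, 193 genes were higher in both, 141 lower in both and 37 opposite (21.1, 19.1 and 40.8 if independent), and r = 0.26 across genes (rho = 0.24). In C201, Gh_D02G0573 went from 4 to 219 counts, a ratio of 176 (counting interval 67.8 to 652), and Gh_D02G0564 from 13 to 709 counts, a ratio of 175 (102 to 331). Both lay in one of 8 runs of neighbouring identifiers that, with 38 scaffold genes, made up 86 of the 1683 higher genes in C201 (copies within such runs can share reads). Gh_A05G2500 went from 1734 to 10 counts in C201, 53.9-fold lower (29.2 to 113). In M120, Gh_Sca015744G01 went from 3 to 124 counts, a ratio of 21.8 (7.31 to 107), and Gh_D02G2248 from 3 to 120 counts, a ratio of 21.1 (7.06 to 104). Gh_A02G0302 went from 164 counts to 0 in M120, 103-fold lower against 3 counts (counting interval from 83.2). Gh_D08G1737 went from 295 to 8 counts in M120, 69.8-fold lower (34.9 to 163). The C201 30 DAI library was the shallowest. With all libraries thinned to its depth, 2704 genes passed the rule in C201 (1240 higher, 1464 lower) and 831 in M120, and with counts divided by the variance factor 1789 and 806 did. With total-count scaling, which moved the log2 ratios of C201 at 30 DAI by -0.13, 1306 of its genes were higher and 2038 lower, and in M120 715 were higher and 801 lower. In M120 the balance also turned with a 4-fold rule (85 and 111) and without the CPM minimum (996 and 1057).

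With the lines as a replicate pair, 0 of 49267 genes passed at 30 DAI in the edgeR test, with 4324 at an unadjusted p under 0.05 and 526 past the DESeq2 test. The gene with the smallest p was Gh_A10G0539, which did not pass: its log2 fold change was 2.76 (SE 0.23, edgeR adjusted p = 0.145), from 16.1 ± 8.28 CPM (SD, n = 2 lines) untreated to 114 ± 75.6 CPM. The count was 1 without M120 untreated, 7 without M120 12 DAI, 12 without C201 12 DAI, 510 without C201 30 DAI, 4832 without M120 30 DAI and 28 without the low-count filter.

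**Figure D2:**
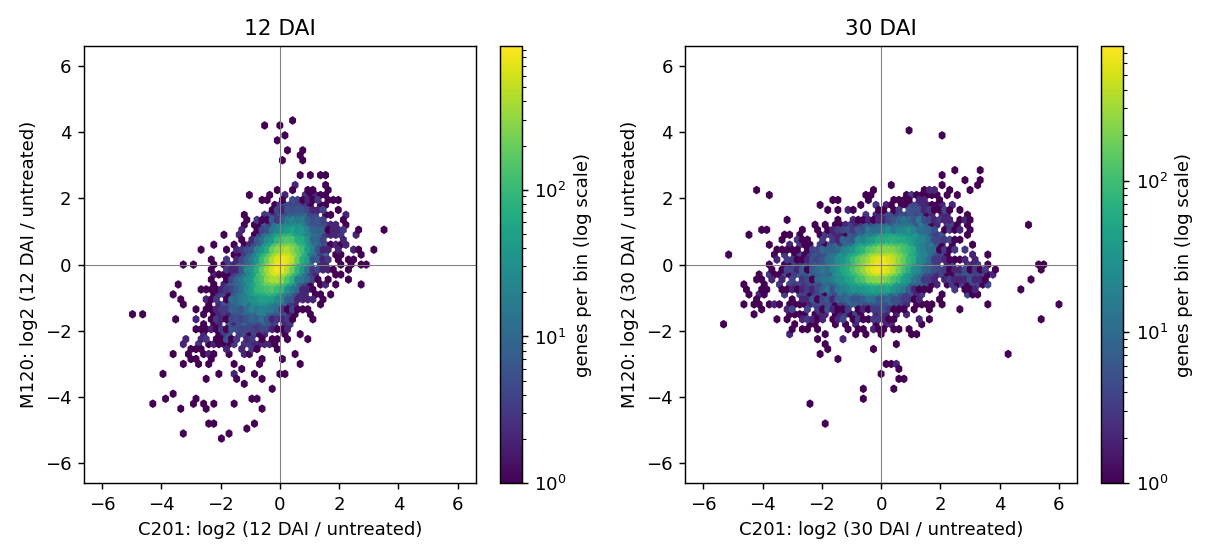
Log2 ratio of inoculated to untreated libraries in C201 (horizontal) and M120 (vertical) for 28761 genes with a mean of at least 5 CPM, at 12 DAI (left) and 30 DAI (right), with color for genes per bin on a log scale. The ratios lie along the diagonal at 12 DAI (r = 0.53) and spread mainly along the C201 axis at 30 DAI (r = 0.26).

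Early and late responses were compared between lines, where no library is shared. Between C201 at 12 DAI and M120 at 30 DAI, r across genes was -0.11, and 32.3% of the 195 genes past the rule in both had the same direction. Of these 195 genes, 14 were higher, 49 lower and 132 opposite (8.21, 13.1 and 22.3 if independent). Between C201 at 30 DAI and M120 at 12 DAI, r was -0.13 and 42.9% of 424 genes had the same direction. There 65 were higher, 117 lower and 242 opposite (24.2, 52.0 and 72.4 if independent). Genes with the same direction thus also exceeded independence, though by less than opposite genes. Within the same stage the shares with the same direction were 97.8% at 12 DAI and 90.0% at 30 DAI.

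The last question was whether inoculation, with 12 and 30 DAI pooled, changed expression within a line and differently between lines. No gene passed the edgeR test in C201 (0 of 51507, 286 at an unadjusted p under 0.05, 0 with DESeq2). No gene passed in M120 (0, with 587 at an unadjusted p under 0.05 and 6, all lower, with DESeq2). The interaction of line and inoculation gave 0 genes (242 at an unadjusted p under 0.05, 0 with DESeq2). Genes with the smallest p, none past the test, were Gh_A10G0685 in C201 (log2 fold change -3.82, SE 0.56, edgeR adjusted p = 1), at 1.53 CPM untreated against 0.0887 and 0.145 CPM inoculated. In M120 it was Gh_A13G1655 (log2 fold change -2.93, SE 0.45, edgeR adjusted p = 1), at 51.1 CPM untreated against 8.59 and 4.77 CPM. In simulation this fit recovered 13 of 100 genes changed 8-fold. Its residual holds the difference between 12 and 30 DAI. With no effect at all, a share of about 0.05 of the genes would have an unadjusted p under 0.05. The counts above lie far below that share, so the test was too strict. Its 0 genes therefore do not speak against a response.

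Chromosomes A11 and D02 (chromosome 14), known to carry root-knot nematode resistance loci in this germplasm, were looked at first for genes that differed between lines. On A11, 28 of 2454 tested genes differed (1.14% against 1.04% elsewhere), 13 higher and 15 lower in M120, and on D02, 16 of 1789 (0.894% against 1.05%), 5 higher and 11 lower. Neither share stood apart (Fisher's exact test, adjusted p = 0.836 for each over 26 chromosomes). One chromosome did: D06 held fewer, 5 of 1651 (0.303% against 1.07%, adjusted p = 0.0209), and without the low-count filter no chromosome passed (smallest adjusted p = 0.145). Fisher's exact test takes genes as independent, so its p is too small where neighbouring genes are related. Among 677 windows of 100 consecutive identifiers, 40 held at least 3 of the genes, and the highest count was 6 of 80 on A03 from 1401 to 1500.

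**Figure D3:**
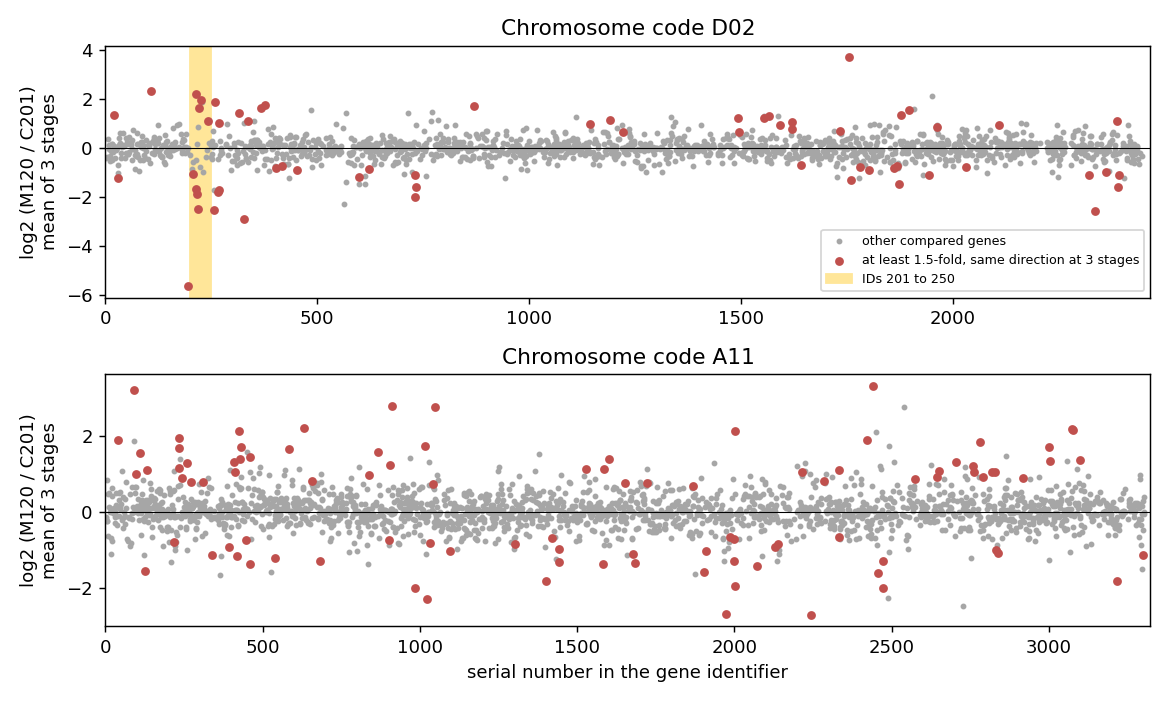
Mean log2 ratio of M120 to C201 over the 3 stages for each compared gene along D02 (top) and A11 (bottom), placed by the serial number in its identifier. Red points differed at least 1.5-fold in the same direction at all 3 stages, and the yellow band marks the window with the highest share of them, 8 of 21 genes.

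No difference between subgenomes was detected in the share of genes that differed between lines: 256 of 23772 tested A genes (1.08%) and 247 of 24757 D genes (0.998%) differed (Fisher's exact test, p = 0.395). Of the genes that fell by 12 DAI, 12 were on A and 11 on D chromosomes (Fisher's exact test, p = 0.836). Homeologs can share reads, so a gene's subgenome and its change are both uncertain to a degree that was not measured.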

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

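Of the tests in this part, those on the D02 segment, the counts of abundant genes and the genes in runs were chosen only after the result was seen. The thinning of libraries was chosen after the data were seen, and its limit was set before the thinned values were computed.

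Gh_A07G1009 had the smallest unadjusted p for a difference of the inoculation response between lines, with an interaction of 5.43 on the log2 scale. Both inoculated C201 libraries lay below untreated C201 (log2 ratio -0.70 at 12 DAI and -0.40 at 30 DAI) and both inoculated M120 libraries above untreated M120 (2.61 and 2.49). It was noted because every library of one line moved against those of the other, and the difference did not pass the edgeR interaction test (adjusted p = 0.99998). M120 untreated had 0.109 CPM, so the change rests on that 1 library. Gh_D10G0648 moved in the same opposite directions, from 0 counts in untreated M120. Its interaction was larger, 7.84, and did not pass either.

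The C201 30 DAI library stood apart from the other 5. Its log2 ratios to untreated C201 had an SD of 0.71, against 0.44 to 0.54 in the other 3 response pairs. Its lower depth of 7451819 counts does not account for this: with all libraries thinned to that depth its SD was still 1.26 times the widest of the others, in 1 random draw and close to the limit of 1.2. A few abundant transcripts do not account for it, since the 10 most abundant genes took 2.88% of its counts. The genes in runs and on scaffolds described next are not the whole of it either, since without them the SD was 1.26 times the widest other. A late response of the susceptible line to the nematode, plant age, and anything else peculiar to 1 library remain open and untested.

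Within that library, 148 genes with a mean of at least 5 CPM had a log2 ratio of at least 2.5 to untreated C201, and 38 of them lay on unplaced scaffolds (25.7% against 0.965% of other genes, Fisher's exact test, p = 3.05e-41, adjusted p = 6.1e-41 over 2 directions). This test takes genes as independent. Its p is too small where genes share reads or regulation. Another 48 lay in 8 runs of at least 3 neighbouring identifiers, such as 9 on A05 from 2826 to 2836 and 9 on A09 from 2514 to 2529. A candidate explanation is one shared source of reads, such as organelle transcripts assigned to organelle copies in the assembly, which would keep these genes in 1 ratio in other libraries too. In M120 at 12 DAI against untreated, the SD of the log2 ratios of the 85 with reads was 0.52. Of 10000 random gene sets matched on expression, 0.14% were as narrow. Simulated genes with 1 ratio had an SD of 0.15, but that simulation held counting error alone. The 86 genes also spread in C201 at 30 DAI (SD 0.73). There the D02 run had log2 ratios from 5.44 to 6.57 and the A07 run from 2.71 to 3.49. Since the set pooled such unlike runs, the test left the question open. Coregulated gene families remain open as well, and gene names, which would decide, were not used here.

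Line differences of at least 1.5-fold crowded in 1 segment of D02. In windows of 50 identifiers, 8 of 21 compared genes in the D02 window ending at 250 (38.1%) differed at least 1.5-fold in the same direction at all 3 stages, against 4.13% of 44166 genes overall. Of the 8, Gh_D02G0213, Gh_D02G0214, Gh_D02G0218 and Gh_D02G0221 averaged at most 3.67 CPM in either line, and the 1.5-fold rule holds no counting interval. The share of 38.1% was the highest of 1320 windows. The next was the adjoining D02 window from 251 to 300 (18.5%), and after it came A11 from 401 to 450 (18.4%). Random scatter of such genes gave a window as high in a share of 3e-05 of 100000 gene orders, a value that is too small where neighbours are related. Of genes past the edgeR line test, the D02 window of 100 identifiers ending at 300 held 4 of 58 tested genes, against 514 of 49267 in all. Its share was therefore high too, although the highest count in such windows was 6 of 80, on A03. Shares of these windows were not tested. Loss of reads from a divergent M120 haplotype against the reference would lower M120. The share of the 8 genes higher in M120 was 0.5 (4 genes, exact 95% interval 0.157 to 0.843, with neighbours taken as independent). Such loss in M120 cannot account for these 4 genes, but it remains open for the 4 lower in M120. The share does not address loss of reads in C201, which would raise the ratio and remains open for the 4 higher in M120. Among these, Gh_D02G0214 and Gh_D02G0221 averaged 0 CPM in C201. A difference in this segment between the lines' parents, and reads shared among tandem copies, remain open, and its place relative to the known resistance locus was not compared.

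For the 514 genes that differed between lines, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest other split gave 99. Both splits with 99 kept the untreated libraries of both lines together and put only the 30 DAI libraries on opposite sides. With stage as a term, both rest on M120 against C201 at 30 DAI alone. They therefore hold a difference between the lines' libraries and are not free of line. The 3 other splits with 1 library of each stage per side gave 0. The splits are too few for a share under 0.05.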

How the results depend on the processing

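Of 110 alternative values, 55 stayed within 1.5 times the main count or share and 55 moved, and the cause was not tested except where fewer libraries or a stricter rule is the setting itself. DESeq2 size factors moved no count by that much, and all 514 line differences remained. Without the low-count filter the counts were 1069 for the line difference (all 514 remained), 215 for 12 DAI and 28 for 30 DAI, and 0 chromosomes stood apart in place of 1. The DESeq2 test gave 1687 (513 of the 514 remained), 677, 526 and, for inoculation in M120, 6. Without the stage term the line test gave 93. Leaving out 1 library gave 263 to 2464 genes for the line difference, 0 to 3332 for 12 DAI and 0 to 4832 for 30 DAI, and 0 for each test of inoculation and the interaction. The highest values came without M120 30 DAI, and without C201 30 DAI they were 2451, 3299 and 510. In both cases the residual comes from the untreated and 12 DAI libraries alone. Leaving out an untreated library ended the contrasts within its line, and these were not run.

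For the pairs in the order C201 at 12 and 30 DAI, M120 at 12 and 30 DAI, and M120 against C201 untreated, at 12 and at 30 DAI, a 4-fold rule left 285, 686, 513, 196, 450, 451 and 1083 genes. The next 3 settings were chosen after seeing the data. Counts divided by the variance factor left 957, 1789, 1572, 806, 1132, 1238 and 2554. Thinning moved all but the 30 DAI pairs of C201 and of the lines, to 971, 1525, 831, 1302 and 1154. Both columns as replicates, in edgeR on the 6 groups, gave 11892, 13918, 14449, 10269, 10412, 11348 and 15429, and for the tests 16739 (line), 17601 (12 DAI), 14689 (30 DAI), 8102 and 10624 (inoculation in C201 and M120) and 6811 (interaction). These count the spread between readings of a library and not between plants, and at 30 DAI M120 against C201 turned to 7846 higher and 7583 lower. Total-count scaling shifted the log2 ratios by -0.13 in C201 at 30 DAI, where the share of higher genes went from 51.0% to 39.1%, and by 0.13 in M120 against C201 at 30 DAI, where it went from 48.9% to 58.8%. The line test itself pairs the libraries by stage, and no other pairing was run, since each group had 1 library. Gene lists, and with them the correlation setting of their test, and the pseudocount planned for normalized values were not run. In simulation, with the same dispersion in all genes, the line test found 12 of 100 genes changed 2-fold. Most differences of that size would be missed under that setting, and the share missed among real genes is not known.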

Other observations

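The tests on neighbouring genes, the group of D02 genes and the genes selected in C201 at 30 DAI were chosen only after the results were seen.

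On D02, 6 genes with serial numbers from 561 to 580 were higher in C201 at 30 DAI by the rule of size, and 4 of them were at least 20-fold higher. These 4 stood at 29.0 to 103 CPM in that library and at no more than 1.81 CPM in any of the other 5. Gh_D02G0573 had no counts in any M120 library. Gh_D06G0237 and Gh_D06G0233, both with 0 counts in untreated M120 and far higher at 12 DAI, were near neighbours as well.

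The genes that differed between lines also lay beside each other. Of 503 on chromosomes, 23 pairs were adjacent among the tested genes, 21 of them in the same direction, against a mean of 5.20 and a highest value of 18 in 100000 random placements (permutation p = 1e-05, the smallest they can give, and adjusted p = 1e-05 over 5 comparisons). The genes past the rule of size showed more adjacent pairs than random placement in each response. The number was 119 against 72.1 in C201 at 12 DAI, 424 against 231 in C201 at 30 DAI, 247 against 158 in M120 at 12 DAI and 95 against 49.1 in M120 at 30 DAI, each with a permutation p = 1e-05. In that order 86, 338, 168 and 70 of the pairs had the same direction, a lower share than for the line difference, and these shares were not tested. Tandem copies that share reads were not told apart from neighbours that each passed on their own.

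Genes with large ratios in C201 at 30 DAI were looked up in M120. Of the 148 genes with a log2 ratio of at least 2.5 in C201, 97 lay within 1.5-fold of untreated in M120 at 30 DAI (65.5%), and of the 209 genes at -2.5 or below, 114 did (54.5%), against 86.0% of all 28761 genes. The median log2 ratio of the 148 was 3.02 in C201 at 30 DAI (quartiles 2.81 and 3.32) and -0.27 in M120 (quartiles -0.51 and 0.01). That of the 209 in M120 was -0.36 (quartiles -0.85 and 0.04), a smaller shift in the same direction as in C201. Together these 148 genes held 21437 CPM in C201 at 30 DAI and 2288 to 2557 CPM in the other libraries. The 209 genes held 883 CPM in C201 at 30 DAI, 8658 CPM in untreated M120 and 6277 CPM in M120 at 30 DAI, and 8053 to 8693 CPM in the other 3. The selection was made on that library, so its own values overstate the change.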
